A study of Mus musculus with 3687 samples.

How the data were processed

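The values are read counts per gene, 1 table column per cell, and 24422 genes, 92 spike-in sequences and 5 summary lines of HTSeq were given for 3687 cells in 12 groups on 15 plates. Per the submitters' processing notes, the deposited counts were made by bcl2fastq, adapter trimming with Trim Galore, alignment to GRCm38/mm10 with STAR and counting with HTSeq, and versions were not given in the sources used here. Per the labels, cells were freed with papain, cleared of debris on Percoll and of dead cells, and index sorted by CD45, CD14, CD64 and CD11b before Smart-Seq2. The reads carry no molecule tags, so reads of 1 gene in 1 cell are not independent molecules. Reads themselves were not used here, and neither were the index sort values, which are not given in the sources used here. The HTSeq line for low alignment quality equalled the line for reads with several alignments in all 3687 cells, the line for unaligned reads was 0 in every cell, and no mitochondrial genes are among the 24422, so a filter on mitochondrial reads was not possible.

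Groups were naive, 9 times after injury, and 2 depleted groups, as the labels give them, and plates were read from the cell identifiers. Because each deposited sample is 1 cell and no label names an animal, cells and plates were not used as replicates and no test, p value or count of changed genes was computed. The groups, the gene lists, the markers, the rule for named genes and the first set of alternatives were fixed before the data were examined. Cells with at least 500 genes and 20000 reads in genes were kept, which left 3657. The median cell had 606166 reads in genes, with a range from 65597 to 6295366, and plate medians ran from 496314 to 927281. Over all cells 53.3% of reads were in genes, 31.8% had several alignments, 11.3% lay outside genes and 2.94% were spike-in.

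Clusters came from log1p counts per 10000, the 2000 most variable genes without the genes of the lists, 30 principal components, 15 neighbours weighted by shared neighbours and Leiden at resolution 1, with seed 0, which gave 25 clusters. An earlier clustering with another package gave 21 clusters and was replaced so that repeats give the same clusters. A marker counted for a cluster where its mean was above the mean of the clusters and at least 25% of the cells had a read. A cluster took the class with the largest share of its markers, at least 3, with 2 exceptions. A cluster stayed unnamed where its 10 leading genes held more markers of another class, and where it was shallow, under 1/3 of the median reads of its plates, with no own marker among the leading genes. This naming rule was written after the clusters were seen. The other definitions of leading genes (pseudocount of 10 CPM in place of 50, mean log level, mean counts) and a depth limit of 1/2 were run as alternatives, 8 combinations in all. Classes carry the ending -like because they rest on RNA markers. Ly6g, Trac, Trbc2, Ighm and Ighd were among the markers and had no line in the table.

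The class was held by different clusters at different times. Naive microglia-like cells were mostly in cluster 0 (395 of 486) and 7 (63), those at 7 d, 21 d and 90 d in cluster 1 (139, 89 and 84 cells), and those at 3 d in clusters 1, 21 and 10 (25, 17 and 11). Cluster 0 was led by P2ry12, Slc2a5, Hspa1a and Tmem119, cluster 1 by Cst7, Apoc1, Serpine2 and Lag3, cluster 5 by Ccl12, Il1rn and Msr1, and cluster 13 by Edn1 and Hbegf. Cluster 9, led by H2-Eb1, H2-Aa and Cd209a, stayed unnamed and was 12.5% of cells at 3 d.

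Shares have exact Clopper-Pearson 95% intervals on cells, which cover counting error only. The classes divide the sorted cells of a group, so a larger share of 1 class makes the others smaller. Shares do not give numbers of cells in the cord. Levels are sums of counts over the cells of a class and group, as CPM of the reads in genes, and log2 ratios are of CPM + 1. This ratio understates a change from a group near 0, so CPM values stand beside it. A class needed 20 cells in both groups. A list is given as the median log2 ratio of its members with at least 10 CPM in 1 of the groups, with the count of members at least 2-fold higher or lower on the same side of each plate, and its percentile among 10000 random lists of the same size matched on expression is tabled as a description of these cells and no test. The 12 lists were homeostatic microglia, disease-associated microglia, interferon response, cell cycle, immediate early and stress, inflammatory cytokines, antigen presentation, glycolysis, oxidative phosphorylation, lipid and cholesterol handling, complement and repair factors. Shares of cells with a read were taken after thinning each cell to 50000 reads. Positions are those of GENCODE vM21.

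Genes were named by a rule: the 10 highest and the 10 lowest log2 ratios among genes with at least 50 CPM in the higher group, whose share of cells with a read moved the same way by at least 20 percentage points and whose value lay on the same side of every plate of the other group. The rule adds the 3 members of each list with the largest change in the direction of the list median, and Ptprc, Itgam, Cd14, Fcgr1 and Cx3cr1 in every group. The rule was written for 6 h, 24 h, 3 d, 7 d, 21 d and 90 d and for the depleted groups. It was applied to 0.5 h, 2 h, cluster 3 and monocyte/macrophage-like cells at 7 d against 6 h after the data were seen. Class markers among the named genes are called markers in the text.

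Alternatives changed 1 choice at a time: the cell filter (none, or 1000 genes and 100000 reads), resolution 0.5 and 2, lists kept in the clustering, classes by marker scores per cell, no cells of the top 2% of genes per plate, mean over cells of CPM, TMM, pseudocount 10, no filter on low values, 50 CPM, thinning to 20000 reads or none, each plate of naive and of 7 d left out, plates VZC001 or VZC002 only, and each naive plate alone as reference for the genes read again. Chosen after seeing the data were the depth limit of 1/2, the definitions of leading genes, cluster 3 counted as microglia-like, the Sparc-read cells, genes named on naive plate 1 and read on plates 2 and 3, the comparisons of cluster 3 and those of monocyte/macrophage-like cells over time. A list median or named gene counted as moved where it lay further from the main value than its standard deviation over plates. Where both groups had 1 plate, the spread over redrawn cells was used instead. Shares, and shares of cells with a read, counted as moved outside the exact interval on cells of the main value, which covers counting error only. Counts of genes read again were judged by a fixed factor of the main count. A value counted as reversed where a sign held on every plate turned. These rules, and the rule for lists that differ between times, were changed after earlier results were seen.

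In a simulated check, 4-fold changes were put on 200 of 3346 genes of the naive sums. All 200 came out past 2-fold with the right sign and 0 of 3146 unchanged genes did, with median log2 ratios of 1.88 and -2.07. The check held counting noise and no noise between cells, plates or animals and no errors of class. At the depth of these sums a 4-fold change could hardly miss the 2-fold limit, so it checks the calculation only. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3 with edgeR 4.0.16. Depleted and non-depleted cells differ in strain label, Cx3cr1/CreER_Rosa26DTA against C57BL/6J, and no depleted group without injury was among the samples.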

Results

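The data were RNA reads of 3687 single CD45+ cells sorted from mouse spinal cord, of which 3657 passed the cell filter. CD45 is the surface protein carried by white blood cells. The groups were uninjured (naive) mice, mice at 9 times from 0.5 h to 90 d after a contusion injury of the cord, and injured mice depleted of microglia, sampled at 7 d and 21 d. The series title asks about a lasting change of microglia, the resident macrophages of the cord. Each group counted as 1 sample, because the labels name plates of cells and no animals, so no difference was tested. Values are given per group, with the range over plates where a group had several (naive 3, injured 7 d 2). Levels are reads summed over the cells of a class and group and scaled by the reads in genes of that sum (CPM). Cells with more reads thus weigh more, and changes are log2 ratios of CPM + 1. Each injured time other than 7 d was on 1 plate, so time and plate cannot be told apart there.

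Microglia-like cells were most of the CD45+ cells without injury, and under 50% of them at 6 h to 7 d, when monocyte/macrophage-like and neutrophil-like cells had larger shares. Their share was 78.5% in naive cord, with a 95% interval of 75.1 to 81.7%, and 72.9% to 81.1% on its plates. It was 45.1% at 6 h (39.4 to 50.8%) and 17.3% at 3 d (13.4 to 21.9%), then 37% at 7 d, 52.3% at 21 d (45.8 to 58.7%) and 39.4% at 90 d. Monocyte/macrophage-like cells were 2.75% in naive cord, 32.6% at 6 h and 45.5% at 36 h (37.4 to 53.7%) and 7.0% at 21 d. Neutrophil-like cells were 2.58% in naive cord and 32.2% at 3 d (27.2 to 37.6%), and T cell-like cells 0.969% and 16.7% at 90 d (12.4 to 21.7%). B cell-like cells were 8.89% of naive cells, 1.79% at 24 h and 10.6% at 90 d, and border-associated macrophage-like cells, of the coverings of the cord, were 4.04% of naive cells and 0 of 154 cells at 36 h (upper limit 2.37%). That limit holds for these clusters only, as this class was 4.44% at 36 h with the strict cell filter, 3.25% at resolution 2 and 13.6% with marker scores. With that filter and at resolution 2, a cluster led by Cd36, Gpnmb, Fabp5 and Spp1 also took this name. In the main clusters, cluster 8 was led by these genes, was named monocyte/macrophage-like and held 5 cells at 36 h. The first 2 values may therefore be a change of name. The plates of 7 d differed by more than counting error, with 20.9% and 56.2% microglia-like cells and 26% and 5.0% neutrophil-like cells, so shares at times with 1 plate carry an unknown error of that order. Classes taken from marker scores per cell gave lower microglia-like shares, 70.6% in naive cord, 21.4% at 6 h, 5.19% at 36 h, 12.8% at 3 d and 22.3% at 90 d, and 29.2% monocyte/macrophage-like cells at 36 h. With the lists kept in the clustering the microglia-like share at 3 d was 8.81%. Because the classes divide the sorted cells, a lower microglia-like share need not mean fewer microglia-like cells in the cord.

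**Figure D1:**
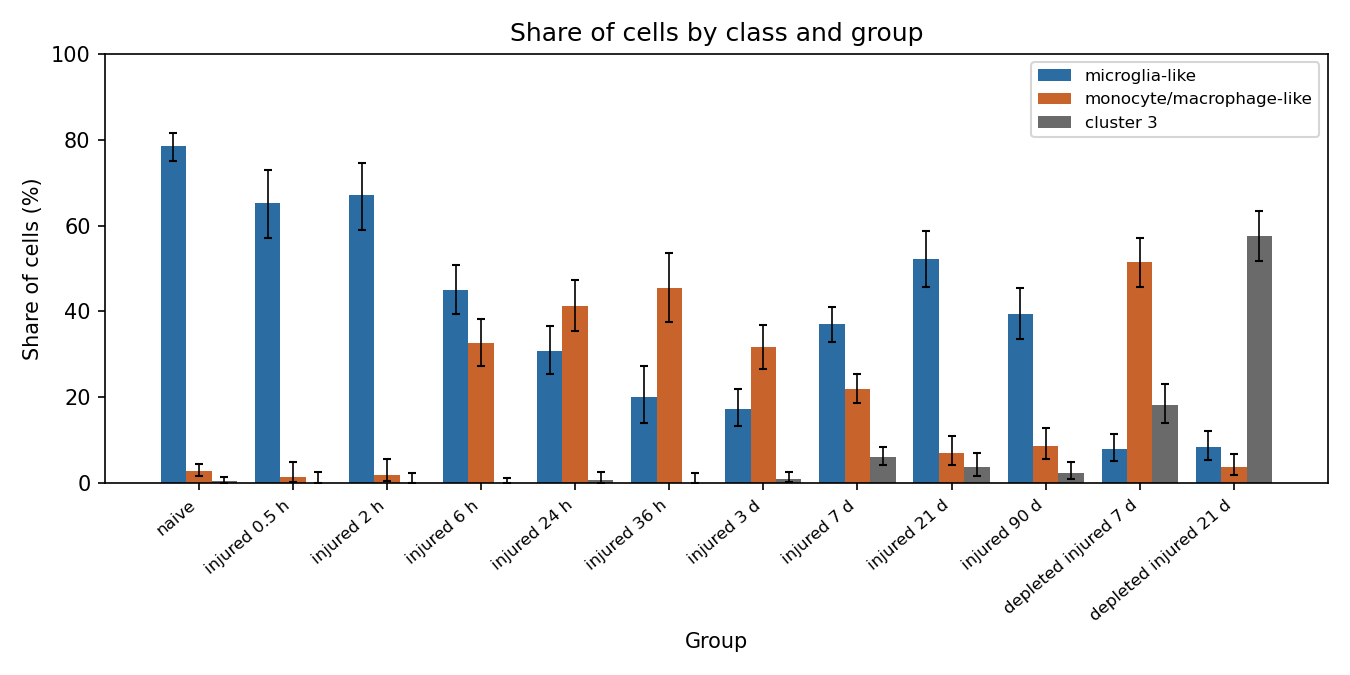
Share of cells (%) that were microglia-like, monocyte/macrophage-like or in the unnamed cluster 3, by group; bars are all cells of a group and lines are exact 95% intervals on cells. Microglia-like cells are 78.5% in naive cord and 17.3% at 3 d (8.81% with the lists kept in the clustering), and cluster 3 reaches 57.6% in depleted injured 21 d.

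In the first hours the cytokine list was higher in microglia-like cells than in naive cord, and Edn1 and Hbegf were among the higher genes at 2 h. The cytokine list had a median log2 ratio against naive of 1.44 at 0.5 h, with 16 of 21 members at least 2-fold higher, and 1.57 at 2 h. Ptgs2, the enzyme that starts prostaglandin synthesis, was at 228 against 23.8 CPM at 0.5 h, the growth regulator Phlda1 at 176 against 10.7 CPM, and the neutrophil attractant Cxcl2 at 639 against 87.4 CPM. By 2 h Edn1, the precursor of the vessel-constricting peptide endothelin, was at 1711 against 25.2 CPM, and the growth factor Hbegf at 1299 against 16.7 CPM. Sphk1, which makes the lipid signal sphingosine phosphate, was at 437 against 0.34 CPM. The repair list, which holds Hbegf, had a median of 0.94 at 0.5 h (0.13 without the filter on low values and 0.16 with members at 50 CPM) and 1.62 at 2 h. Of the genes that were lower at 2 h, Tifab, which restrains immune signalling, was at 0.0447 against 159.6 CPM, and the transcription factor Hhex at 7.63 against 301 CPM. Most of these cells were in cluster 7 at 0.5 h (74 of 96) and cluster 13 at 2 h (94 of 102), and with 2 other definitions of a cluster's leading genes cluster 7 stayed unnamed, which gave a cytokine median of 1.24 at 0.5 h and turned Cxcl2 to -0.31. The 2 h plate also had 15.1% of its reads from spike-in RNA, against 1.35 to 4.27% on the others, and TMM scaling shifted the log2 ratios there by 0.39.

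At 6 h Il1rn and Msr1 were among the genes that were higher than in naive cord, and the homeostatic list was lower. Il1rn, which blocks the receptor of interleukin 1, was at 4961 against 27.4 CPM (73% against 2.88% of cells with a read after thinning). Msr1, a scavenger receptor for lipids and debris, was at 642 against 1.29 CPM, and Slc7a11, which imports cystine for antioxidant defence, at 423 against 0.303 CPM. Npy, a neuropeptide, had 818 CPM and no read in naive microglia-like cells. The homeostatic list had a median of -2.19 (-2.20 to -1.86 against the single naive plates), with 16 of 21 members at least 2-fold lower. Within it Selplg, a ligand for selectins, was at 214 against 4423 CPM and the adhesion receptor Adgrg1 at 54.3 against 363 CPM. Hpgd, which degrades prostaglandins, was at 18.8 against 766 CPM. The interferon list had a median of 1.59, and 3.22 without naive plate 1, with Rsad2, an antiviral enzyme, at 395 against 4.03 CPM. The cell cycle median of -1.15 turned positive without the cells richest in genes (0.25), and was -3.01 without naive plate 1.

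At 24 h Msr1 was at 2039.9 CPM, with a read in 94.2% against 0.617% of cells, and the monocyte/macrophage markers Arg1, which breaks down arginine, and Fn1, which encodes fibronectin, were at 377 against 1.12 CPM and 447 against 1.77 CPM. Slc2a5, the fructose carrier used as a microglia marker, was at 1.15 against 635 CPM. The homeostatic median was -1.98, with Adgrg1 at 9.19 against 363 CPM and Entpd1, which degrades extracellular ATP, at 25.8 against 496 CPM. Of the disease-associated list Spp1, the secreted protein osteopontin, was at 7276 against 491 CPM and Lpl, a lipase, at 1959 against 122 CPM, although the list median was 0.02. Glycolysis genes were higher, with a median of 1.32 and 13 of 16 members up at least 2-fold, among them Pkm, which makes pyruvate, at 2064 against 283 CPM. At 36 h the homeostatic median was -2.41 in 31 cells, and interferon (2.45), glycolysis (2.11), cell cycle (2.07) and oxidative phosphorylation (1.61) medians were all above 0 against each naive plate, with interferon at 0.98 under the strict cell filter. Most of the microglia-like cells from 6 h to 36 h were in cluster 5, which had 3 of 10 microglia markers above the mean of clusters, so their assignment rests on fewer markers than at other times. The cell cycle median at 24 h was 0.88, and -0.44 without naive plate 1.

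With the main clusters, cell cycle genes had their highest median in microglia-like cells at 3 d. That median was 2.83 (1.97 to 4.21 against the single naive plates), with 27 of 30 members at least 2-fold higher, and 1.58 with the lists kept in the clustering. Rrm2, which makes the building blocks of DNA, was at 175 against 1.0 CPM, Birc5, needed for chromosome segregation, at 137 against 5.36 CPM, and the mitotic cyclin Ccnb2 at 146 against 7.41 CPM. Spp1 was at 17822 against 491 CPM, with a read in 89.5% against 7.2% of cells, and the growth factor Igf1 at 131 against 7.03 CPM. The disease-associated median was 1.32 and the homeostatic median -1.38. Hspa1a and Hspa1b, which encode the stress-induced chaperone HSP70, were at 65.3 against 1858 CPM and 4.9 against 90.6 CPM. The 57 cells were 17.3% of the group, and 17 of them were in the dividing cluster 21. With the lists kept in the clustering, the cluster led by Birc5, Ccnb2 and Top2a (59 cells over all groups) was named monocyte/macrophage-like. Which class held the dividing cells thus depended on the clustering.

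At 7 d Igf1, Gpnmb, Cst7 and Apoc1 were among the genes that were higher in microglia-like cells than in naive cord, and the disease-associated list was higher. Igf1 was at 358 against 7.03 CPM (4.32 to 10.3 on the naive plates), a log2 ratio of 5.48, with a read in 45.5% against 1.85% of cells. Gpnmb, a glycoprotein of lysosomes, was at 471 against 9.66 CPM, Cst7, an inhibitor of lysosomal proteases, at 539 against 23 CPM, and the apolipoprotein gene Apoc1 at 215 against 4.37 CPM. In GENCODE vM21 on GRCm38, Igf1 lies on chromosome 10 from 87858265 to 87937042, Gpnmb on chromosome 6 from 49036546 to 49070929, Cst7 on chromosome 2 from 150570415 to 150578944 and Apoc1 on chromosome 7 from 19689481 to 19692660. The disease-associated median was 1.80 (1.37 to 1.92 against the single naive plates), with 17 of 26 members at least 2-fold higher and none lower. The homeostatic median was -0.99, less far below 0 than at 6 h to 3 d. Txnip, which restrains glucose uptake, was at 227 against 1449 CPM, and Slc2a5 at 122 against 635 CPM. Fn1, at 195 against 1.77 CPM, and Folr2, at 86.4 against 0.922 CPM, are markers of monocytes/macrophages and of border-associated macrophages. Plates that share the prefix VZC001 or VZC002 held both groups, and within them the homeostatic median was -1.21 and -0.67 and the cell cycle median 1.96 and -0.05. The cell cycle median over all plates, 0.55, was -0.05 without naive plate 1 and -0.39 in the Sparc-read cells, those with a read of the microglia marker Sparc and none of Ccr2, Ly6c2 or Ms4a7.

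The disease-associated genes were also higher than in naive cord at 21 d and 90 d. The disease-associated median was 2.20 at 21 d and 1.96 at 90 d (1.48 to 2.22 against the single naive plates), and the homeostatic median -1.13 and -1.05. Gpnmb was at 471, 622 and 1687 CPM at 7 d, 21 d and 90 d, and Igf1 at 358, 470.3 and 321 CPM. Of the complement genes, C3, the central complement protein, was at 29.9, 38 and 184 CPM against 0.244 in naive cells, and C4b at 251 against 1.55 CPM at 90 d. Saa3, an acute-phase protein, was at 338 against 0.0247 CPM, and Gpx3, a secreted peroxidase, at 343 against 1.17 CPM. Slc2a5 was at 54.7 against 635 CPM and Selplg at 917 against 4423 CPM. Gimap6, a GTPase of immune cells, was at 8.71 CPM (115 in naive cells), and Klhdc8b had no read at 90 d (116 CPM in naive cells). Of the genes named at 90 d, Fn1 and Ms4a7 are markers of other macrophage classes. The disease-associated median in the Sparc-read cells was 1.99. These were 52 of the 104 microglia-like cells at 90 d and 421 of 486 in naive cord. The other cells had no Sparc read or had a Ccr2, Ly6c2 or Ms4a7 read.

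The genes named at 7 d were read again later. All 10 higher genes were at least 2-fold above naive at 21 d and at 90 d, with median log2 ratios of 5.24 and 5.35 after 5.47 at 7 d. Single genes were nearer to naive than at 7 d, as Folr2 was at 86.4, 8.95 and 6.54 CPM at 7 d, 21 d and 90 d, Ctla2a at 95.3, 33.9 and 18 CPM, and Ch25h at 176, 169 and 36.3 CPM. Of the 10 lower genes, all 10 were at least 2-fold below naive at 21 d and 8 at 90 d, and Arrdc3, an arrestin, was at 260.1 CPM at 90 d against 181 in naive cells. Each naive plate alone as the reference gave counts within 1.5 times of these. The lower genes include Hspa1a and Hspa1b of the immediate early and stress list, for which handling of the naive plates was not excluded. Every time was read against the same naive cells, so such an effect would return at each time. Txnip and Gm15441, also among the lower genes, overlap on opposite strands of chromosome 3 and may not be separate losses. With genes named against naive plate 1 and read against plates 2 and 3, 10 of 10 higher genes were again 2-fold above naive at both times, and 7 of 10 lower genes 2-fold below at each. Directly against 7 d, the disease-associated median was 0.14 at 21 d and -0.01 at 90 d, and the homeostatic median 0.01 and -0.14. The disease-associated value at 21 d was above 0 in every alternative, and the other 3 changed sign with processing. Cell cycle genes were lower than at 7 d (-1.81 at 21 d and -1.18 at 90 d), as was oxidative phosphorylation (-0.40 and -0.67). The interferon list was lower at 90 d (-0.99), with 12 of 24 members at least 2-fold lower, and at -0.54 with members at 50 CPM and -0.46 with marker scores. The cell cycle value at 21 d was -0.84 with cells weighted equally, -0.50 with members at 50 CPM and -0.13 with the lists kept in the clustering, and that at 90 d was -0.91 and -2.43 without plate 1 and plate 2 of 7 d.

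**Figure D2:**
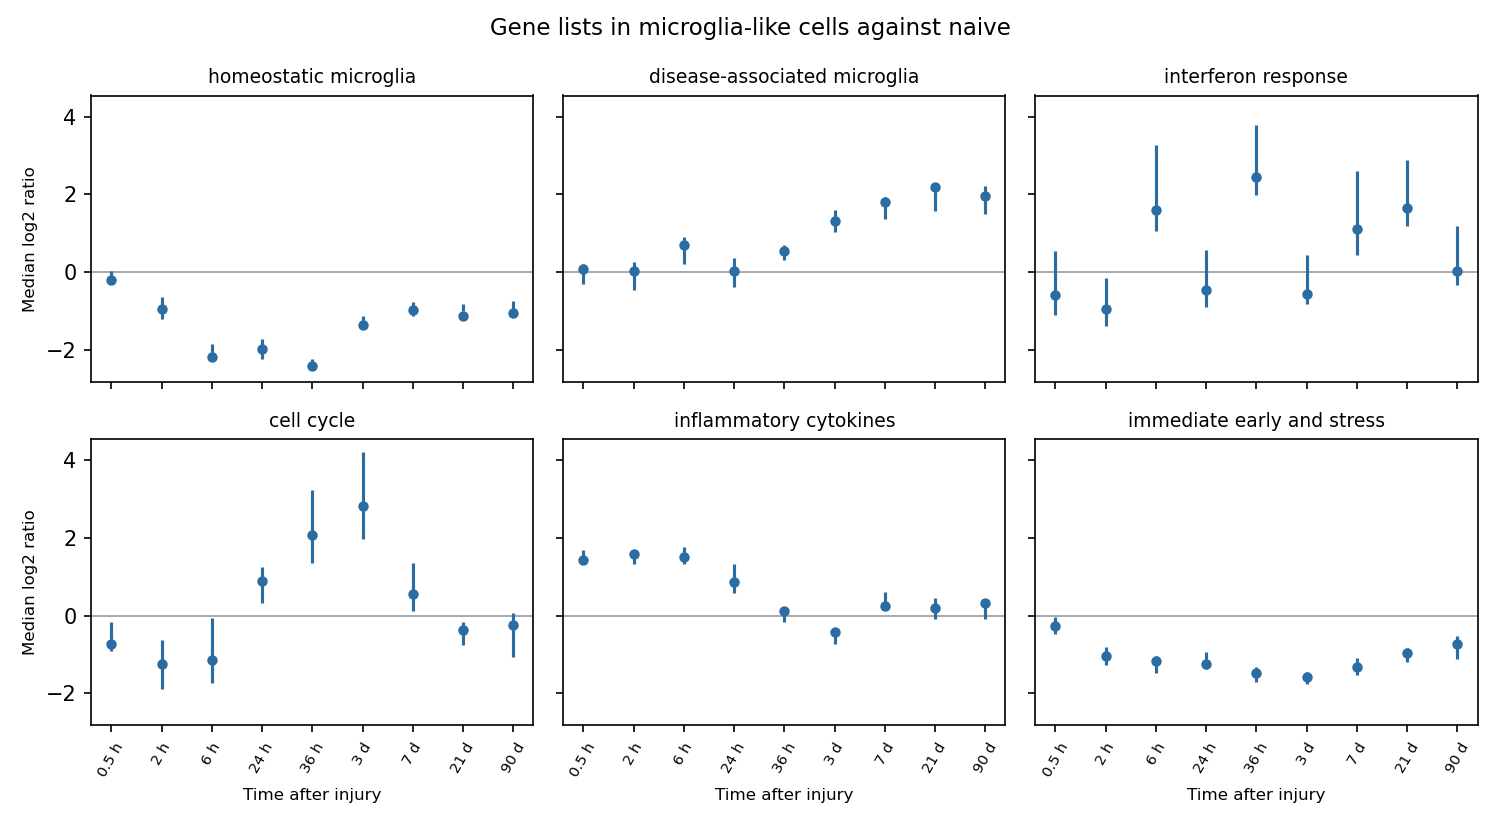
Median log2 ratio of 6 gene lists in microglia-like cells against naive (vertical axis) by time after injury (horizontal axis, not to scale); points are against all naive cells and lines span the values against the single naive plates. The homeostatic list is lowest at 36 h (-2.41) and stays near -1 to 90 d (-1.05), while the disease-associated list is 1.80 at 7 d and 1.96 at 90 d.

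Immediate early and stress medians were below 0 against naive cells at every time, from -0.26 at 0.5 h to -1.59 at 3 d and -0.72 at 90 d. Against the single naive plates the 90 d value ran from -1.11 to -0.52. The value at 0.5 h was smaller than that range, and TMM scaling shifted log2 ratios there by 0.20, so it was not resolved. B cell-like cells also had a lower median at 90 d (-0.54), although their clusters also differed from those of naive cells. Lipid and cholesterol handling was 1.44 at 3 d and 1.35 at 90 d, with Ch25h, which makes 25-hydroxycholesterol, at 248 against 7.79 CPM at 3 d. Antigen presentation was 0.81 at 7 d and 1.00 at 90 d, with H2-Aa, a class II chain, at 129 against 1.76 CPM at 7 d. The antigen median at 7 d was 0.47 with marker scores, 0.38 within the VZC002 plates and 0.50 without plate 1 of 7 d or in Sparc-read cells, and at 90 d 0.57 with members at 50 CPM and 0.61 with pseudocount 10. Glycolysis was 2.11 at 36 h, 1.63 at 3 d and 0.77 at 90 d, and oxidative phosphorylation 1.61, 1.43 and 0.22 (0.38 at 90 d with TMM scaling). The complement list was 0.38 at 0.5 h, 0.57 at 7 d and 0.31 at 90 d, with 0.33 at 21 d. TMM scaling gave 0.89 at 0.5 h and 0.48 at 90 d for this list, the value at 0.5 h was 0.082 without the filter on low values, and that at 90 d was 0.11 in Sparc-read cells. Repair factors were 0.82 at 3 d (0.03 without naive plate 1), 0.39 at 7 d and 0.86 at 90 d (0.19 without the filter on low values and 0.42 without naive plate 1). At 7 d the repair median was -0.01 without naive plate 1, 0.81 without plate 2 and -0.02 within the VZC002 plates, so no direction was read from it. The interferon list was 1.10 at 7 d (1.95 without naive plate 1 and 0.66 without plate 2), 1.64 at 21 d and 0.03 at 90 d, the last with values from -0.34 to 1.18 against the single naive plates. Interferon medians at 0.5 h (-0.59), 24 h (-0.46) and 3 d (-0.57) were 0.33, 0.69 and 0.53 without naive plate 1, and disease-associated medians at 0.5 h, 2 h and 24 h lay on both sides of 0 against the single naive plates. Changes in the lists that were smaller than the range over naive plates, such as complement at 6 h (-0.05), were not resolved.

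The genes behind the sort and Cx3cr1, named in the strain label of the depleted mice, differed between times. Cd14, a co-receptor for bacterial products, was at 2436 CPM in naive microglia-like cells, 14572 at 2 h and 4288 at 90 d. Cx3cr1, the fractalkine receptor, was at 4007, 1018 CPM at 24 h and 2898 at 90 d. Ptprc, which encodes CD45, was at 357 in naive cells, 81.4 at 24 h and 386 at 90 d. Itgam, which encodes CD11b, was at 402, 106 and 436 CPM in naive, 2 h and 90 d cells, and Fcgr1, which encodes CD64, at 339, 102 and 203 CPM. In the depleted groups Cx3cr1 was at 233 CPM at 7 d and 1791 at 21 d, and Cd14 at 721 and 1063.

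With cluster 3 unnamed, the depleted groups had few microglia-like cells and a larger share of cluster 3. At 7 d they also had a larger share of monocyte/macrophage-like cells. Microglia-like cells were 7.82% at 7 d with depletion (24 of 307, interval 5.07 to 11.4%) against 37% without, and 8.33% at 21 d (24 of 288, interval 5.41 to 12.1%) against 52.3%. Monocyte/macrophage-like cells were 51.5% at 7 d with depletion (45.7 to 57.2%) against 21.9% without, and 3.82% against 7.0% at 21 d. No direction was read for border-associated macrophage-like cells, which were 0.326% against 1.05% at 7 d from these clusters, but 32.2% against 10.7% with marker scores, 35.5% against 10.3% at resolution 2 and 25.5% against 4.71% with the strict filter, and at 21 d 0.694% with depletion, or 28.1% with marker scores. The shares at resolution 2 and with the strict filter came with a change of name. There a cluster led by Cd36, Gpnmb, Fabp5 and Spp1, as cluster 8 was, took the border-associated name. Cluster 8 itself was named monocyte/macrophage-like. A cluster led by Mrc1 stayed separate from it, with 85 and 73 cells over all groups. Cluster 3, led by Gpnmb, Ms4a7, Gpx3 and Apoe, was 18.2% against 6.13% at 7 d, and 57.6% (51.7 to 63.4%) against 3.7% at 21 d. T cell-like cells were 17.7% at 21 d with depletion (51 of 288) and 7.82% without (19 of 243). The classes divide the cells of a group, and microglia-like cells were 24 of 288 and 127 of 243 there. A smaller microglia-like share alone makes other shares larger, so a rise of T cell-like cells was not read from this. The strain label goes with the depletion label in every cell, so strain, plate and depletion cannot be told apart. Counting cluster 3 as microglia-like gave 26.1% at 7 d and 66% at 21 d with depletion. Without depletion, microglia-like cells and cluster 3 were 52.3% and 3.7% at 21 d, so the share counted this way was larger with depletion. At 7 d it stayed smaller, as the 2 were 37% and 6.13% without depletion. A stricter depth limit on clusters gave 1.30% and 1.74% microglia-like cells with depletion, and marker scores 12.8% at 21 d. Marker scores, a higher resolution and a strict cell filter gave 31.3%, 26.4% and 28.1% monocyte/macrophage-like cells at 7 d with depletion. Without depletion these were 11.7%, 13.5% and 14.7%. At the higher resolution and with the strict filter, the cluster led by Cd36, Gpnmb, Fabp5 and Spp1 was not counted among them.

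The microglia-like cells of the depleted groups had lower homeostatic and cytokine medians, by an amount that depended on how the class was drawn. Whether they were microglia that outlasted the depletion was not tested. At 7 d their homeostatic median was -2.11 against cells of injured mice with microglia, and cytokines were at -2.54, immediate early and stress genes at -2.39 and interferon genes at -1.63, while cell cycle was 1.79. Of the 24 cells 4 were in the dividing cluster 21, against 6 of 211 without depletion, and the cell cycle median was 0.16 with cluster 3 counted in and 1.27 with cells weighted equally. With cluster 3 counted in, the homeostatic, cytokine, stress and interferon medians at 7 d were -1.14, -1.56, -1.10 and -0.75. Gpnmb was at 10058 against 471 CPM, and the monocyte/macrophage markers Arg1, Chil3, a lectin, and F13a1, a clotting factor, at 841 against 0.146 CPM, 242 against 0.809 CPM and 511 against 16.4 CPM. Lag3, an immune receptor, and Plxdc2, a membrane protein, had no read with depletion against 867 and 732 CPM without. At 21 d the homeostatic median was -1.03, cytokines -1.90 and oxidative phosphorylation 0.76, with Gpnmb at 5172 against 622 CPM and Lyz2, lysozyme, at 22282 against 4006 CPM. Slc2a5 and Adgrg1 had no read at 21 d with depletion, against 143 and 126 CPM without. Of these cells, 20 of 24 at 7 d and 19 of 24 at 21 d were in cluster 10, which had no microglia marker among its leading genes. Its cells had a median of 285276 reads against 634556 for its plates. The sums still held 9544247 reads in genes at 7 d and 11363941 at 21 d. At their levels without depletion, Lag3, Plxdc2, Slc2a5 and Adgrg1 would have had many reads in these sums. Reads of 1 gene in 1 cell are not independent molecules, however, and each sum rests on 24 cells. Median genes per cell were 1309.5 at 7 d and 1747 at 21 d with depletion, against 2657 and 2482 without. These genes were also chosen for low values in this same comparison. Depth thus stays open as a reason why they had no read. The disease-associated median at 21 d was 0.64, -0.02 with classes from marker scores and -0.06 with cluster 3 counted in, and oxidative phosphorylation was -0.20 and 0.12 and cytokines -0.48 and -1.08 in these. Fewer than 20 of these cells were left in each depleted group under the strict filter, with the lists kept in the clustering, at the stricter depth limit and with naming by mean counts, and at 7 d with marker scores, so no median was given there. Without a cell filter and at resolution 0.5, where only shares were planned, each group also kept fewer than 20. In these 2 and with the lists kept, a cluster led by Apoe, Cst7 and Lyz2 stayed unnamed. Its leading genes held more markers of another class than of microglia.

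Monocyte/macrophage-like cells at 7 d had less antigen presentation with depletion. The list median was -1.09 (-1.34 to -0.76 against the single plates of 7 d), with 9 of 17 members at least 2-fold lower and none higher. The class II genes H2-Eb1, H2-Aa and H2-Ab1 were at 48.9 against 1146 CPM, 126 against 1909 CPM and 215 against 2337 CPM, and Cd74, the class II chaperone, at 389 against 2124 CPM. H2-Aa lies on chromosome 17 from 34282744 to 34287823 and H2-Ab1 on chromosome 17 from 34257689 to 34269419. Cell cycle was -1.28, with Cenpf, a centromere protein, at 2.59 against 15.5 CPM, and oxidative phosphorylation -0.63. Spp1 was higher with depletion at 24026 against 10313 CPM, and Csf1, a growth factor of macrophages, at 64.4 against 15.5 CPM. Wdfy1, an adaptor of endosomal receptors, was at 72.9 against 14 CPM, and Abcc3, an efflux pump, at 180.0 against 60.5 CPM. The depleted cells held more of cluster 8 (77 of 158) than those without depletion (48 of 125), and the complement genes C1qa and C1qc, higher at 1.30 and 1.19, were lower under a strict cell filter at -1.37 and -0.85. With the class II cluster 9 counted in, under another definition of leading genes, the antigen median was -1.09, and without plate 1 of 7 d Cenpf was -0.45 and oxidative phosphorylation -0.41. The cell cycle median was -2.29 under the strict cell filter. In 11 monocyte/macrophage-like cells at 21 d with depletion, levels were not compared.

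Cluster 3 had some microglial markers near 0 while others were present, in a comparison added after the clusters were seen. In depleted injured 21 d against microglia-like cells of injured 21 d, its disease-associated median was -0.07, with 5 of 26 members at least 2-fold higher, 6 lower and 15 between. Its homeostatic median was -1.10, with 11 of 20 members at least 2-fold lower and none higher. The microglia markers Sparc, a matrix protein, Siglech, a sialic acid receptor, and Sall1, a transcription factor, were at 5.85 against 1949 CPM, 2.3 against 436 CPM and 0.00617 against 67.9 CPM. The markers Fcrls, a receptor of the Fc family, Tmem119, a membrane protein, and P2ry12, a nucleotide receptor, were at 2538 against 2184 CPM, 758 against 1016 CPM and 341 against 1129 CPM. Higher genes were Gdf3, a growth factor, at 268 CPM with no read in the microglia-like cells, Cd93, a receptor for dying cells, at 101 against 0.0335 CPM, and Mgst1, a glutathione transferase, at 293 against 9.31 CPM. Cytokine (-1.03) and interferon (-0.77) medians were lower. The cluster stayed unnamed because its leading genes held Ms4a7, a marker of border-associated macrophages, and no microglia marker. Microglia was still the class with the largest share of markers in it, 5 of 10.

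Monocyte/macrophage-like cells had lower interferon and higher disease-associated and repair genes after 6 h, in comparisons that were also added later. Against 6 h, the disease-associated median was 0.72 at 24 h, 1.54 at 3 d and 1.91 at 7 d, and the repair median 1.92, 2.05 and 2.23. Interferon medians were -1.10, -0.92 and -1.24. At 7 d Gpnmb was at 2493 against 2.16 CPM and Cx3cr1 at 226 against 0.567 CPM, while Il1r2, a decoy receptor for interleukin 1, was at 55 against 1817 CPM. The cells were mostly of cluster 6 at 6 h (81 of 99), cluster 2 at 24 h (89 of 115), and clusters 8, 2 and 6 at 7 d (48, 39 and 35 of 125). Lists kept in the clustering turned the cell cycle median at 3 d from -1.49 to 2.30. The repair median was 0.52 at 24 h with members at 50 CPM and 0.27 at 3 d without the filter on low values, and at 7 d the strict cell filter gave 1.11 for the disease-associated and -0.78 for the interferon list.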

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

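Of the 5 tests in this part, 2 were written before their result was seen, those on the stress list in B cell-like cells and on Sparc-read cells, and 3 after. For the stress list, the bound itself was taken from the microglia-like median already seen.

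Several lists lay on opposite sides of naive at different times, on every naive plate, and each difference was not tested. The interferon list was 2.45 at 36 h and -0.95 at 2 h, cell cycle 2.83 at 3 d and -1.24 at 2 h, and inflammatory cytokines 1.57 at 2 h and -0.43 at 3 d. Antigen presentation was 1.00 at 90 d and -0.36 at 24 h, oxidative phosphorylation 1.61 at 36 h and -0.54 at 2 h, and complement 0.57 at 7 d and -0.56 at 2 h. With TMM scaling the oxidative and complement values at 2 h were -0.16 and -0.17, on a plate with 15.1% of reads from spike-in RNA, the cell cycle value at 2 h was -3.64 without naive plate 1, and the interferon value at 36 h was 0.98 under the strict cell filter.

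Between the depleted groups, against injured mice of the same day, disease-associated genes were 0.64 at 21 d and -0.068 at 7 d, interferon 0.36 and -1.63, and cell cycle -0.67 and 1.79, each difference again not tested. The disease-associated signs depended on processing, with -0.02 at 21 d with marker scores, -0.06 there with cluster 3 counted in, and 0.073 at 7 d with cells weighted equally. At 7 d the interferon list stayed below 0 (-0.75 with cluster 3 counted in) and cell cycle above 0 (0.16 there), while the interferon value at 21 d was -0.69 with cluster 3 counted in and the cell cycle value at 21 d 0.32 with marker scores.

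A transgene sequence outside the mouse gene set was read in 31.6% of cells of depleted injured 7 d and 39.2% of depleted injured 21 d, and in none of the other groups. Of neutrophil-like, T, B and NK cell-like cells of these plates, 0 of 132 had such a read (upper limit 2.76%), against 64.9% of cluster 3 (58.2 to 71.1%). This argues against an even spread of reads between wells, under a bound written after the result was seen. Depth was not matched here, as T cell-like cells at 21 d had a median of 366797 reads and cluster 3 had 858414. Among monocyte/macrophage-like cells of depleted injured 7 d, 57.6% of those with a Cx3cr1 read had a transgene read (34 of 59, 44.1 to 70.4%) and 12.1% of those without (12 of 99, 6.42 to 20.2%), as a transgene that goes with the Cx3cr1 gene would give. Of microglia-like cells of depleted injured 21 d 17 of 24 had a Cx3cr1 read and 3 a transgene read, and of T cell-like cells there 7 of 51 and 0. Deeper reading raises both reads and was not matched, so the cause of the link, tested in 1 class, stays open.

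Immediate early and stress genes were highest in naive microglia-like cells, although the difference from 0.5 h was not resolved. This could be handling of the naive plates or a state of the cells. In B cell-like cells the list median at 90 d against naive was -0.54 (-0.97 to -0.35 over naive plates), so handling that acts on every cell type fits, with the plate at -0.35 just above the bound of -0.36. At 0.5 h and 2 h the B cell-like medians were -0.01 and -0.48. The B cell-like clusters differed between groups, with 42 of 55 naive cells and 17 of 28 at 90 d in cluster 17, and 19 of 21 in cluster 14 at 0.5 h and at 2 h, so a difference between B cell clusters stays open as a cause.

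The disease-associated list at 90 d could come from macrophages, or their RNA, counted as microglia-like. Cells with a Sparc read and no Ccr2, Ly6c2 or Ms4a7 read were 52 of 104 microglia-like cells at 90 d and 421 of 486 naive ones. In them the list median was 1.99 (1.62 to 2.20 over naive plates). This met the bound set before for macrophages, or their RNA, not being the cause. The choice of cells cannot exclude macrophage RNA that lacks Ccr2, Ly6c2 and Ms4a7, so the value shows only that the list was also high in cells without these reads. Without the shallow cluster 10 it was 1.96 (1.51 to 2.23). A macrophage that had gained Sparc and lost Ms4a7 would pass this test, so the origin of the cells stays open.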

How the results depend on the processing

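No tests were run in this part, and the alternatives on the depth limit, the definitions of leading genes, the count of cluster 3 and the Sparc-read cells were chosen after seeing the data. Below naive in every alternative run were the homeostatic medians from 2 h to 90 d (-1.14 to -0.86 at 90 d), and above naive were the disease-associated medians at 6 h, 36 h, 3 d, 7 d, 21 d and 90 d (1.78 to 2.12 at 90 d), the cytokine medians at 0.5 h and 2 h, and the cell cycle median at 3 d (1.58 to 3.54). Antigen presentation in depleted 7 d macrophages stayed lower (-1.34 to -0.76). Of the list medians in planned comparisons 2382 alternative values stayed within the spread, 384 moved and 30 reversed, and in the added ones 720, 59 and 1. A reversal was counted only where the main sign held on every plate or over redrawn cells. Values that stayed or moved can thus also have turned sign. Of shares 1005 stayed and 103 moved, of named genes 8406 stayed, 1227 moved and 20 reversed, of shares of cells with a read 362 stayed and 118 moved, and the 12 counts of genes read again stayed. TMM shifted log2 ratios by 0.39 at 2 h, 0.28 at 7 d, 0.20 at 0.5 h, 0.17 at 21 d, 0.16 at 90 d, -0.13 at 36 h, 0.19 in depleted 21 d, -0.12 at 21 d and 90 d against 7 d, 0.12 in macrophages at 3 d against 6 h, and less elsewhere. Without a cell filter and at resolutions 0.5 and 2, shares alone were computed, as planned, and no filter or resolution 0.5 left under 20 microglia-like cells in each depleted group. Under 20 cells, and so no median, were left for microglia-like cells of both depleted groups with the strict filter, the lists in the clustering, the stricter depth limit, naming by mean counts or a Sparc read, of depleted 7 d with marker scores, and at 36 h with marker scores or a Sparc read. Clusters led by the same genes as cluster 3 were found in the other clusterings (288 cells without a filter, 321 with the strict filter, 298 and 237 at the other resolutions, 277 with the lists kept), but its comparisons were run on the main clusters only. Depth limits the depleted microglia-like cells, with a median of 269458 reads at 7 d, and the neutrophil-like cells there, with 165697. Below, macrophages are monocyte/macrophage-like cells, medians are log2 ratios against naive or, in depleted groups, against the same day, list names are shortened, and the cause was not tested for any of the values.

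With TMM scaling, homeostatic medians were -0.010 at 0.5 h, -0.56 at 2 h, -0.70 at 7 d, -0.96 at 21 d, -0.88 at 90 d, -0.11 at 21 d against 7 d (reversed) and -0.26 at 90 d against 7 d. Disease-associated medians were 0.53 at 2 h, 2.08 at 7 d, 0.017 at 21 d against 7 d, -0.13 at 90 d against 7 d and -0.14 in depleted 7 d. Stress medians were -0.64 at 2 h, -1.05 at 7 d and -0.22 in depleted 7 d macrophages. Cytokine medians were 1.65 at 0.5 h, 1.95 at 2 h and -0.39 at 90 d against 7 d. Antigen medians were 0.49 at 0.5 h, 0.32 at 2 h, -0.062 at 36 h (reversed), 1.10 at 7 d and 0.84 at 21 d. Glycolysis medians were 0.90 at 2 h and 1.07 at 7 d. Oxidative medians were -0.19 at 0.5 h, -0.16 at 2 h, 1.16 at 7 d, 0.64 at 21 d, 0.38 at 90 d, -0.51 at 21 d against 7 d, -0.79 at 90 d against 7 d and 0.29 in depleted 7 d. Lipid medians were 0.44 at 2 h, 0.20 at 24 h, 1.34 at 7 d, 1.55 at 21 d and 0.20 in depleted 21 d. Complement medians were 0.89 at 0.5 h, -0.17 at 2 h, 0.0033 at 6 h (reversed), 0.86 at 7 d, 0.50 at 21 d, 0.48 at 90 d, -0.37 at 21 d against 7 d and -0.086 at 90 d against 7 d. Repair medians were 0.85 at 21 d and -0.27 at 21 d against 7 d.

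With cells weighted equally, homeostatic medians were -2.55 at 36 h, -1.64 at 3 d, 0.0037 at 21 d against 7 d, -2.22 in depleted 7 d and 0.046 in depleted 7 d macrophages. Disease-associated medians were 0.0042 at 90 d against 7 d and 0.073 in depleted 7 d (reversed). Interferon medians were 0.032 at 21 d against 7 d and -2.19 in depleted 7 d. Cell cycle gave -0.84 at 21 d against 7 d and 1.27 in depleted 7 d. Stress medians were -1.78 at 3 d, -3.34 in depleted 7 d and -0.22 in depleted 7 d macrophages. Cytokine medians were 1.77 at 2 h, 0.35 at 36 h, -0.15 at 90 d against 7 d and -3.46 in depleted 7 d. Antigen medians were -0.021 at 36 h (reversed), -0.057 at 3 d and 0.78 at 21 d. Glycolysis medians were 1.04 at 6 h, 1.97 at 3 d, 0.10 at 21 d against 7 d and 0.77 in depleted 7 d. Oxidative medians were -0.21 at 0.5 h, 0.54 at 6 h, 1.05 at 24 h, 1.66 at 3 d, -0.26 at 21 d against 7 d, -0.47 at 90 d against 7 d and 0.51 in depleted 7 d. Lipid medians were 0.11 at 2 h, -0.15 at 6 h (reversed), 1.30 at 36 h and 0.083 in depleted 7 d. Complement medians were 0.022 at 6 h (reversed), 0.30 at 36 h, 0.21 at 3 d and -0.17 at 21 d against 7 d. Repair medians were 0.073 in depleted 7 d macrophages (reversed).

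With members at 50 CPM, homeostatic medians were -0.091 in depleted 7 d macrophages (reversed). Interferon medians were 0.58 at 0.5 h, 0.63 at 3 d and -0.54 at 90 d against 7 d. Cell cycle gave -0.50 at 21 d against 7 d and 2.43 in depleted 7 d. Stress medians were -0.21 in depleted 7 d macrophages. Cytokine medians were -0.16 at 90 d against 7 d. Antigen medians were -0.035 at 0.5 h (reversed), -0.54 at 2 h, -0.058 at 36 h (reversed), 0.53 at 21 d and 0.57 at 90 d. Glycolysis medians were 0.93 at 6 h. Oxidative medians were 0.46 at 6 h, -0.60 at 90 d against 7 d and 0.31 in depleted 7 d. Lipid medians were 0.73 at 24 h, 1.22 at 36 h, 1.48 at 7 d and 1.89 at 21 d. Complement medians were -0.28 at 6 h, -0.18 at 36 h, 0.51 at 7 d, 0.30 at 21 d and -0.15 at 21 d against 7 d. Repair medians were 0.16 at 0.5 h, 2.45 at 6 h, 0.89 at 36 h, 1.46 at 7 d, 0.86 at 21 d, 1.32 at 90 d and -0.16 at 21 d against 7 d.

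With marker scores, shares were microglia-like 70.6% in naive, 40.1% at 2 h, 21.4% at 6 h, 11.8% at 24 h, 5.19% at 36 h, 12.8% at 3 d, 29.2% at 7 d, 34.6% at 21 d, 22.3% at 90 d, 1.3% in depleted 7 d and 12.8% in depleted 21 d, plasmacytoid dendritic cell-like 1.45% in naive, 3.29% at 2 h, 2.87% at 24 h, 3.9% at 36 h, 3.65% at 3 d, 7.82% at 21 d, 4.92% at 90 d and 5.21% in depleted 21 d, border-associated macrophage-like 8.6% at 24 h, 13.6% at 36 h, 5.78% at 3 d, 10.7% at 7 d, 3.41% at 90 d, 32.2% in depleted 7 d and 28.1% in depleted 21 d, monocyte/macrophage-like 29.2% at 36 h, 25.2% at 3 d, 11.7% at 7 d and 31.3% in depleted 7 d, B cell-like 6.6% in depleted 21 d. Homeostatic medians were -1.79 at 6 h, -1.21 at 3 d, -1.03 at 21 d, -0.86 at 90 d, 0.080 at 21 d against 7 d, 0.060 at 90 d against 7 d (reversed) and 0.049 in depleted 7 d macrophages. Disease-associated medians were 0.043 at 21 d against 7 d and -0.14 at 90 d against 7 d. Interferon medians were -0.46 at 90 d against 7 d. Stress medians were -0.33 in depleted 7 d macrophages. Cytokine medians were -0.48 in depleted 21 d. Antigen medians were -0.28 at 2 h, -0.54 at 24 h, 0.47 at 7 d, 0.068 at 21 d against 7 d (reversed) and 0.35 at 90 d against 7 d. Glycolysis medians were 0.96 at 6 h. Oxidative medians were -0.33 at 2 h, -0.71 at 90 d against 7 d and -0.20 in depleted 21 d (reversed). Lipid medians were 0.091 at 0.5 h, 0.48 at 6 h, 0.51 at 24 h and 0.40 in depleted 21 d. Complement medians were -0.24 at 6 h, 0.15 at 24 h, 0.24 at 90 d and -0.17 at 21 d against 7 d. Repair medians were 0.044 at 6 h, -0.32 at 21 d against 7 d, 0.44 at 90 d against 7 d, 0.99 in depleted 21 d and 0.19 in depleted 7 d macrophages (reversed). Reversed genes were Mmp12 at -0.35 at 24 h, Rsad2 at -0.47 at 21 d, Cox7b at -0.35 in depleted 21 d, Mcm7 at 0.24 in depleted 21 d, Nlrc5 at 1.46 in depleted 21 d, Uqcr11 at -0.44 in depleted 21 d, C1qa at -0.23 in depleted 7 d macrophages and Mmp12 at 0.56 in depleted 7 d macrophages.

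With cluster 3 counted in, shares were microglia-like 43.1% at 7 d, 26.1% in depleted 7 d and 66% in depleted 21 d. Homeostatic medians were 0.11 at 21 d against 7 d, -0.0061 at 90 d against 7 d and -1.14 in depleted 7 d. Disease-associated medians were 0.013 at 21 d against 7 d, -0.078 at 90 d against 7 d and -0.027 in depleted 7 d. Interferon medians were -0.75 in depleted 7 d. Cell cycle gave 0.16 in depleted 7 d. Stress medians were -1.10 in depleted 7 d. Cytokine medians were -0.12 at 21 d against 7 d, -1.56 in depleted 7 d and -1.08 in depleted 21 d. Antigen medians were -0.34 in depleted 7 d. Glycolysis medians were 0.35 in depleted 7 d. Oxidative medians were -0.64 at 90 d against 7 d, 0.058 in depleted 7 d and 0.12 in depleted 21 d. Lipid medians were 1.49 at 7 d and 0.10 at 21 d against 7 d. Complement medians were 0.50 at 7 d, -0.17 at 21 d against 7 d and 0.11 at 90 d against 7 d. Repair medians were 0.88 at 7 d, 0.57 at 21 d, -0.29 at 21 d against 7 d and 0.96 in depleted 7 d. Reversed genes were H2-Ab1 at 0.22 in depleted 21 d.

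Without the low-value filter, homeostatic medians were -0.026 at 21 d against 7 d (reversed) and -0.19 at 90 d against 7 d. Cell cycle gave -1.19 at 90 d and -2.35 at 90 d against 7 d. Stress medians were -2.49 in depleted 7 d. Antigen medians were 0.18 at 2 h and -0.016 at 36 h (reversed). Lipid medians were 0.10 at 0.5 h, -0.092 at 6 h (reversed), 0.020 at 24 h, 0.39 at 36 h, 0.98 at 3 d, 0.66 at 21 d and 0.22 in depleted 7 d. Complement medians were 0.082 at 0.5 h and -0.80 at 2 h. Repair medians were 0.13 at 0.5 h, 0 at 36 h, 0 at 3 d, 0.48 at 21 d and 0.19 at 90 d.

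Naming by mean counts, shares were microglia-like 67.7% in naive, 14.3% at 0.5 h, 28.9% at 7 d, 41.6% at 21 d, 1.3% in depleted 7 d and 1.74% in depleted 21 d, T cell-like 0.68% at 0.5 h, 0 at 2 h and 1.08% at 24 h. Homeostatic medians were -0.040 at 21 d against 7 d (reversed). Disease-associated medians were 0.90 at 0.5 h and -0.045 at 90 d against 7 d. Interferon medians were -1.86 at 0.5 h. Cell cycle gave -2.99 at 2 h. Cytokine medians were 1.24 at 0.5 h, 1.93 at 2 h, 0.38 at 36 h, 0.58 at 7 d and 0.62 at 90 d. Antigen medians were 0.15 at 36 h. Oxidative medians were -0.19 at 0.5 h and -0.66 at 90 d against 7 d. Lipid medians were 0.78 at 0.5 h, 0.16 at 2 h and 0.81 at 36 h. Complement medians were 0.27 at 0.5 h, 0.36 at 36 h, 0.24 at 21 d, 0.39 at 90 d and -0.33 at 21 d against 7 d. Repair medians were 1.17 at 24 h, 0.78 at 36 h and 1.06 at 7 d. Reversed genes were Cxcl2 at -0.31 at 0.5 h.

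Naming with pseudocount 10, shares were microglia-like 68.3% in naive and 15% at 0.5 h. Homeostatic medians were -0.050 at 21 d against 7 d (reversed). Disease-associated medians were 0.89 at 0.5 h, 0.18 at 21 d against 7 d and -0.035 at 90 d against 7 d. Interferon medians were -1.86 at 0.5 h. Cell cycle gave -2.99 at 2 h. Cytokine medians were 1.24 at 0.5 h, 1.94 at 2 h, 0.34 at 36 h and 0.56 at 90 d. Oxidative medians were -0.20 at 0.5 h, -0.71 at 90 d against 7 d and 0.34 in depleted 7 d. Lipid medians were 0.77 at 0.5 h and 0.16 at 2 h. Complement medians were 0.27 at 0.5 h. Repair medians were 1.13 at 24 h, 1.02 at 7 d and 0.80 at 21 d. Reversed genes were Cxcl2 at -0.31 at 0.5 h.

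Naming by mean log level, shares were T cell-like 0.68% at 0.5 h, 0 at 2 h and 1.08% at 24 h, monocyte/macrophage-like 53.9% at 36 h, 44.1% at 3 d and 27.8% at 7 d. Homeostatic medians were 0.080 in depleted 7 d macrophages. Stress medians were -0.37 in depleted 7 d macrophages. Complement medians were 0.53 in depleted 7 d macrophages. Repair medians were 0.022 in depleted 7 d macrophages (reversed).

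With lists in the clustering, shares were microglia-like 8.81% at 3 d, 31.2% at 7 d, 0 in depleted 7 d and 3.12% in depleted 21 d, monocyte/macrophage-like 18.6% at 7 d. Homeostatic medians were -1.02 at 3 d, -0.016 at 21 d against 7 d (reversed) and -0.028 in depleted 7 d macrophages (reversed). Disease-associated medians were 0.091 at 21 d against 7 d. Cell cycle gave 1.58 at 3 d, -0.13 at 21 d against 7 d and 2.30 in macrophages at 3 d against 6 h (reversed). Stress medians were -1.35 at 3 d and -0.22 in depleted 7 d macrophages. Antigen medians were 0.28 at 36 h, -0.051 at 3 d and 0.055 at 21 d against 7 d (reversed). Glycolysis medians were 1.32 at 3 d and 0.14 at 90 d against 7 d. Oxidative medians were 1.22 at 3 d and -0.60 at 90 d against 7 d. Lipid medians were 0.46 at 24 h and 1.29 at 36 h. Complement medians were 0.39 at 36 h and 0.25 at 21 d. Reversed genes were Rrm2 at -0.051 at 7 d, Serpine2 at -1.93 in depleted 7 d macrophages and Slco2b1 at -0.026 in depleted 7 d macrophages.

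Without gene-rich cells, homeostatic medians were 0.023 at 21 d against 7 d and 0.036 in depleted 7 d macrophages. Disease-associated medians were -0.024 at 90 d against 7 d. Cell cycle gave 2.26 in depleted 7 d. Antigen medians were 0.11 at 36 h. Oxidative medians were -0.71 at 90 d against 7 d and 0.38 in depleted 7 d. Lipid medians were 1.18 at 36 h and 1.21 at 7 d. Complement medians were 0.48 at 36 h.

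In Sparc-read cells, homeostatic medians were -1.96 at 6 h and -0.94 at 21 d. Cell cycle gave -0.39 at 7 d. Antigen medians were -0.45 at 2 h, 0.50 at 7 d and 0.78 at 90 d. Oxidative medians were 1.13 at 24 h, 1.63 at 3 d and 0.30 at 21 d. Lipid medians were 0.16 at 2 h, 0.63 at 24 h, 0.91 at 7 d and 1.10 at 21 d. Complement medians were 0.037 at 6 h (reversed), 0.29 at 21 d and 0.11 at 90 d. Reversed genes were Birc5 at -2.18 at 7 d, Cfp at -0.59 at 7 d, Rrm2 at -0.99 at 7 d and Mmp12 at -0.34 at 90 d.

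With pseudocount 10, homeostatic medians were -1.91 at 6 h, -2.25 at 36 h and -1.85 in depleted 7 d. Interferon medians were -1.10 in depleted 7 d. Cell cycle gave 1.30 in depleted 7 d. Stress medians were -2.25 in depleted 7 d. Cytokine medians were -2.28 in depleted 7 d. Antigen medians were 0.61 at 90 d. Oxidative medians were 1.29 at 3 d, -0.53 at 90 d against 7 d and 0.32 in depleted 7 d. Lipid medians were 0.78 at 36 h.

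At the stricter depth limit, shares were microglia-like 31.3% at 7 d, 45.3% at 21 d, 1.3% in depleted 7 d and 1.74% in depleted 21 d. Homeostatic medians were -2.27 at 36 h and 0.023 at 21 d against 7 d. Disease-associated medians were -0.015 at 90 d against 7 d. Antigen medians were 0.18 at 36 h. Oxidative medians were -0.45 at 21 d against 7 d and -0.63 at 90 d against 7 d. Complement medians were 0.35 at 36 h, 0.26 at 21 d, -0.32 at 21 d against 7 d and -0.013 at 90 d against 7 d.

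With the strict cell filter, shares were neutrophil-like 0.699% at 2 h, 1.13% at 6 h, 6.17% at 24 h, 14.8% at 36 h, 10.4% at 21 d, 10.6% at 90 d and 6.83% in depleted 7 d, border-associated macrophage-like 4.44% at 36 h, 6.08% at 3 d, 4.71% at 7 d and 25.5% in depleted 7 d, monocyte/macrophage-like 24.7% at 3 d, 14.7% at 7 d, 28.1% in depleted 7 d and 1.84% in depleted 21 d, NK cell-like 0 at 90 d, microglia-like 1.8% in depleted 7 d and 4.04% in depleted 21 d. Homeostatic medians were -0.020 at 21 d against 7 d (reversed) and 0.15 in depleted 7 d macrophages. Disease-associated medians were -0.0039 at 90 d against 7 d. Interferon medians were 0.98 at 36 h and 0.55 in depleted 7 d macrophages. Cell cycle gave -2.29 in depleted 7 d macrophages. Stress medians were -0.31 in depleted 7 d macrophages. Antigen medians were -0.078 at 36 h (reversed). Glycolysis medians were -0.078 in depleted 7 d macrophages. Oxidative medians were -0.64 at 90 d against 7 d. Lipid medians were 0.74 at 36 h. Complement medians were 0.30 at 21 d. Repair medians were -0.52 in depleted 7 d macrophages. Reversed genes were C1qa at -1.37 in depleted 7 d macrophages and C1qc at -0.85 in depleted 7 d macrophages.

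Within VZC001, cell cycle medians were 1.96 at 7 d. Cytokine medians were 0.81 at 7 d. Glycolysis medians were 0.53 at 7 d. Lipid medians were 1.27 at 7 d. Complement medians were 0.50 at 7 d.

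Within VZC002, homeostatic medians were -0.67 at 7 d. Antigen medians were 0.38 at 7 d. Lipid medians were 1.36 at 7 d. Repair medians were -0.021 at 7 d (reversed).

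Without a cell filter, shares were microglia-like 31.7% at 7 d, 1.29% in depleted 7 d and 2.06% in depleted 21 d.

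At resolution 0.5, shares were microglia-like 31.9% at 7 d, 45.7% at 21 d, 1.3% in depleted 7 d and 1.74% in depleted 21 d.

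At resolution 2, shares were border-associated macrophage-like 3.25% at 36 h, 9.73% at 3 d, 10.3% at 7 d, 35.5% in depleted 7 d and 4.51% in depleted 21 d, monocyte/macrophage-like 23.1% at 3 d, 13.5% at 7 d, 26.4% in depleted 7 d and 1.74% in depleted 21 d.

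Leaving out 1 plate, antigen medians spanned -0.38 to -0.0080 at 21 d against 7 d, 0.69 to 0.75 at 21 d, 0.0018 to 0.062 at 36 h, -0.28 to -0.035 at 3 d, 0.50 to 0.98 at 7 d, -0.34 to -0.024 at 90 d against 7 d and 0.77 to 0.97 at 90 d. Cell cycle spanned -3.05 to -0.23 at 0.5 h, -2.08 to -0.15 at 21 d, -0.44 to 1.41 at 24 h, -3.64 to -1.05 at 2 h, -3.01 to -0.073 at 6 h, -2.43 to -0.91 at 90 d against 7 d and -1.18 to -0.082 at 90 d. Complement medians spanned -0.22 to -0.15 at 21 d against 7 d, 0.29 to 0.32 at 21 d, -0.071 to 0.15 at 24 h, 0.46 to 0.58 at 7 d, -0.47 to -0.35 in depleted 7 d and 0.38 to 0.57 in depleted 7 d macrophages. Disease-associated medians spanned 0.052 to 0.054 at 90 d against 7 d, -0.046 to -0.00099 in depleted 7 d and -0.00069 to 0.60 in depleted 7 d macrophages. Glycolysis medians spanned -0.11 to 0.14 at 21 d against 7 d, 0.77 to 0.87 at 6 h and 0.48 to 0.92 at 7 d. Homeostatic medians spanned -0.29 to 0.10 at 0.5 h, 0.037 to 0.043 at 21 d against 7 d, -1.13 to -0.86 at 21 d, -1.09 to -0.67 at 7 d, -0.10 to -0.021 at 90 d against 7 d, -1.10 to -0.86 at 90 d and 0.078 to 0.20 in depleted 7 d macrophages. Stress medians spanned 0.22 to 0.45 at 21 d against 7 d, -1.68 to -1.39 at 36 h, -1.77 to -1.54 at 3 d, -1.44 to -1.09 at 6 h and -0.24 to -0.21 in depleted 7 d macrophages. Cytokine medians spanned 1.48 to 1.62 at 0.5 h, -0.28 to -0.047 at 21 d against 7 d, 1.22 to 1.62 at 6 h, 0.27 to 0.76 at 7 d and -0.49 to 0.16 in depleted 7 d macrophages. Interferon medians spanned -0.0091 to 0.39 at 21 d against 7 d, -0.73 to 0.53 at 3 d, 1.08 to 3.22 at 6 h and -0.31 to 1.05 at 90 d. Lipid medians spanned 0.037 to 0.45 at 0.5 h, 0.061 to 0.28 at 21 d against 7 d, 1.26 to 1.71 at 21 d, 0.28 to 0.41 at 24 h, 0.68 to 1.11 at 36 h, 0.95 to 1.26 at 7 d, -0.18 to 0.23 at 90 d against 7 d, 0.32 to 0.59 in depleted 7 d and 0.14 to 0.44 in depleted 7 d macrophages. Oxidative medians spanned -0.47 to -0.39 at 21 d against 7 d, 0.72 to 0.88 at 24 h, -0.66 to -0.66 at 90 d against 7 d, 0.37 to 0.39 in depleted 7 d and -0.71 to -0.41 in depleted 7 d macrophages. Repair medians spanned -0.27 to 0.20 at 21 d against 7 d, 0.55 to 0.79 at 21 d, -0.019 to 1.10 at 24 h (reversed), 0.026 to 1.10 at 3 d, -0.012 to 0.81 at 7 d (reversed), 0.010 to 0.52 at 90 d against 7 d and -0.56 to -0.10 in depleted 7 d macrophages. B cell-like shares spanned 0.385% to 3.86% at 7 d and 7.35% to 11.7% in naive. NK cell-like shares spanned 0.769% to 5.79% at 7 d and 0.377% to 1.45% in naive. Microglia-like shares spanned 20.9% to 56.2% at 7 d. Neutrophil-like shares spanned 5.00% to 26% at 7 d.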

Other observations

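No test was run in this part, so none was chosen after a result was seen. Spike-in RNA gives a measure of RNA per cell outside the comparisons above. Microglia-like cells had a median of 13.3 gene reads per spike-in read in naive cord (11.9 to 15.7 over plates), 3.57 at 2 h, 30.1 at 24 h, 48.1 at 3 d, 28.5 at 7 d and 28.9 at 90 d. Monocyte/macrophage-like cells had 27.6 at 6 h and 48.2 at 3 d, and cluster 3 had 66.3 in depleted injured 7 d. B cell-like cells had 7.74 in naive cord and 1.4 at 2 h, so the low ratio at 2 h was not limited to microglia-like cells, and an amount of spike-in that differs between plates was not tested. Median genes per microglia-like cell were 2079.5 in naive cord and 3300.0 at 3 d.

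Cells with a transgene read were 75% of cluster 3 in depleted injured 7 d and 61.4% in depleted injured 21 d. They were 29.1% of monocyte/macrophage-like and 20.8% of microglia-like cells at 7 d, and 45.5% and 12.5% at 21 d. Cluster 3 was also present without depletion, as 6.13% of cells at 7 d, 3.7% at 21 d and 2.27% at 90 d. Dendritic-like genes led cluster 9, with H2-Eb1, Cd209a and Flt3, a growth factor receptor of dendritic cells, and it was 12.5% of cells at 3 d.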
